A study of Mus musculus with 2 samples.

How the data were processed

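DNase I accessibility was measured by DNase-seq in kidney tissue of female B6CASTF1/J mice aged 8 to 10 months, per the labels. DNase-seq sequences the ends that the enzyme DNase I leaves where chromatin is open, so that peaks mark accessible DNA and footprints mark short stretches inside them that were cut less. B6CASTF1/J is a first-generation cross between a C57BL/6J and a CAST/EiJ parent, so each animal carries 1 chromosome set that differs from the C57BL/6J reference. Reads of the CAST/EiJ set may map less well, which may lower the signal of a region or hide a peak, and this could not be tested from the deposited lists. The labels number the 2 libraries as biological replicates 1 and 2 and give them separate tissue samples under 1 shared donor entry. Whether the tissue came from separate animals is not stated, so the spread between the libraries may be partly technical. There is 1 group and no untreated or other-tissue sample.

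The authors deposited 4 measured files per library, all on assembly mm10 and each made from the filtered alignments of that library, with no pooling of the libraries, per the file headers of the accompanying text list. Some were also made from further input files that were not used here. The aligner, the peak caller, the footprint caller and their versions are not given in the sources used here. Both peak lists give each peak a signal value as deposited by the authors. In each library, 100% of these values were whole multiples of a single step within a tolerance of 0.05 steps. The step was 0.00827 in replicate 1 and 0.00834 in replicate 2. If the signal is in tags per M tags (M, mega) and a step stands for 1 tag, the libraries held 120.9 M and 119.9 M tags, which is an inference from the values. The third file lists a false discovery rate (FDR, a q-value in the deposited files) for runs of bases, with no value listed above 0.05. The footprint file carries a constant 0.01 for every footprint, a p-value or q-value level set by the authors and not a value per site, per the values in the deposited files.

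The 2 peak lists of a library differ in threshold. Set against the FDR file of the same library, the highest FDR at the best base of any peak was 0.0499 in both longer lists, and 0.000989 and 0.000985 in the shorter lists. Of the shorter lists, 98.9% and 98.5% of peaks overlapped a peak of the longer list. The longer list was the main peak set by a rule set before the data were examined. Within it, 1882 peaks of replicate 1 and 3142 of replicate 2 overlapped another peak of the same list. Overlapping peaks that held both libraries were joined into 1 shared region, which took the highest signal of each library.

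Coordinates are 1-based on mm10 (GRCm38). Genes, transcription start sites (TSS) and sequence came from the GENCODE M21 annotation and the GRCm38.p6 genome. As a check of the match between sequence and annotation, 59215 of 59255 annotated start codons read ATG. A promoter window was the 500 bases on each side of any protein-coding TSS. This TSS may lie inside the gene, as it does for the peaks of Krt10, Egf, Kcnj1, Pdgfra and Plin1. A promoter was called open where a region shared by both libraries overlapped such a window. Regions were assigned to promoter, exon, intron or intergenic sequence in that order.

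Peaks were called shared when they overlapped by at least 1 base, and this share was set beside 100 seeded random placements of the peaks on their chromosomes. For each of 20 gene lists (242 genes in all), the number of open promoters was tested against all other protein-coding genes on chromosomes 1 to 19 and X with a two-sided Fisher's exact test. Odds ratios have 0.5 added to each count, and their intervals are exact and without it. Shared regions outside promoter windows were counted in each gene body with 10 kb added on each side. The list median was set against 10000 random lists of the same size matched on gene length in 20 bins, with a two-sided percentile p. For 25 consensus motifs, footprints shared by both libraries were set against windows of the same width moved by 100 bases (Fisher's exact test). Control windows lay inside the same region and touched no footprint. Then 5 bases were added on each side of both, so a tested control window may reach into a footprint or past the region. The test did not use the pairing of footprint and control window. A motif was called where the adjusted p was under 0.05 and the ratio was at least 1.5 or at most its inverse. Where a motif had no control window, the ratio was taken against a floor of 3 windows and is a lower bound. All p-values were adjusted by the Benjamini-Hochberg method within each family (20 lists, 20 lists and 25 motifs). Genes and sites are the units of these tests, not samples. They describe these libraries, and with 1 group no test across samples was made. Intervals for shares are exact binomial and those for rates exact Poisson, at the 95% level, and cover counting error only.

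The lists held markers of proximal tubule, thick ascending limb, distal convoluted tubule, collecting duct principal cells, intercalated cells, podocytes, endothelium, stroma and mural cells, immune cells, urothelium, adrenal cortex, adipocytes, erythroid cells, hepatocytes, neurons, striated muscle, germ cells and keratinocytes, with kidney transcription factors and housekeeping genes. The genes named were chosen by rule. From each list these are up to 3 members with the highest mean promoter signal and up to 2 members, first in list order, with no promoter peak in either library. To these were added the 10 genes with the most shared regions, the nearest genes of the 10 strongest shared regions outside promoters, and Xist with the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y. A few genes that the rule takes are not reported here. Lists, motifs, tests and the rule were set before the data were examined. Tests and values chosen later are named as such where they are given.

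The scripts were tested on simulated data. The promoter test recovered 90 of 100 simulated lists with few open promoters and called 2 of 300 unchanged lists. Lists with more open promoters were not simulated. The region count test recovered 15 of 15 lists and called 2 of 45 unchanged ones. The motif test recovered 5 of 5 motifs and called 0 of 20 unchanged ones. Its simulated footprints and controls had the same base content, unlike the data, so calls that come from base content were not examined. In each test the simulated change had a fixed size, so the counts do not show how often smaller changes would be missed. Alternatives covered the shorter peak list, the stronger 50% of peaks by signal, reciprocal overlap, other window widths and flanks, CpG-poor promoters only, other control windows and each library alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.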

Results

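The data are 2 DNase-seq libraries of adult female mouse kidney, biological replicates 1 and 2 of a single group. They map accessible DNA in a tissue whose main cells are the epithelia of the nephron. The comparisons the design allows are between the replicates, and within the tissue between gene groups, genomic features and motifs. Values of a region are the deposited signal, given as the mean ± SD of the 2 libraries (n = 2).

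The longer lists held 137083 peaks over 27.6 Mb in replicate 1 and 125000 peaks over 26.2 Mb in replicate 2. The median width was 200 bases in both, and the median signal was 0.744 and 0.800. At an FDR under 0.05 the libraries listed 44.3 and 43.8 Mb, of which 34.2 Mb was listed in both.

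The first comparison asked how far the replicates found the same open regions. In replicate 1, 72.4% of peaks overlapped a peak of replicate 2, and in replicate 2, 79.2% overlapped a peak of replicate 1. Random placement gave at most 2.10% and 2.36%. Strong peaks were found in both libraries almost without exception. Of peaks with a signal of 2 or more, 98.7% of replicate 1 and 99.3% of replicate 2 were shared, against 23.8% and 31.5% of peaks with a signal under 0.25. Joined across libraries, the overlapping peaks made 96746 shared regions. Across these regions, which are not independent replicates, the signals of the libraries correlated with a Spearman rho of 0.865. The SD of the log2 ratio between libraries was 0.63, above the median SD of 0.19 that counting error alone would give if a step of the signal is 1 tag. The signal differed more than 2-fold in 11.9% of regions.

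**Figure D1:**
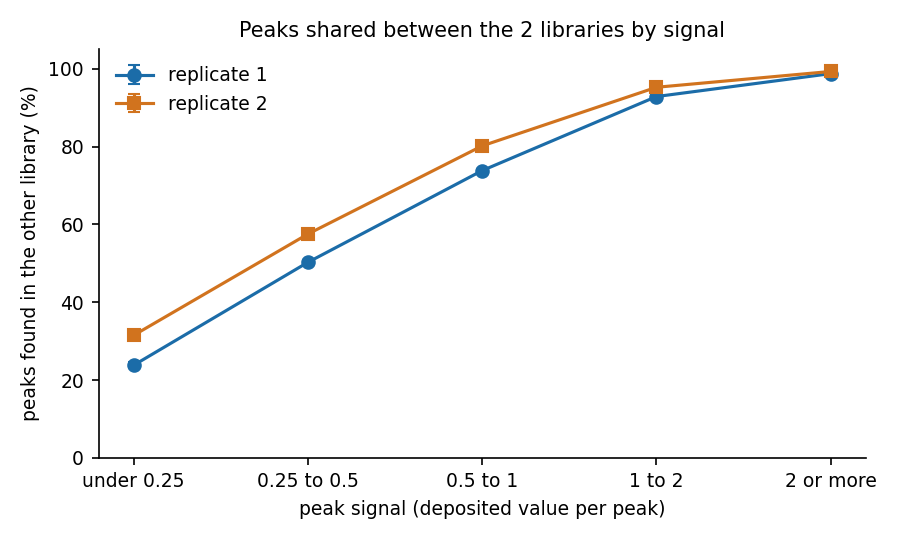
Share of peaks (y axis, percent) that overlapped a peak of the other library, in 5 ranges of the deposited signal (x axis), for replicate 1 (circles) and replicate 2 (squares), with exact 95% binomial intervals that are mostly smaller than the symbols. The share rises from 23.8% and 31.5% in the weakest range to 98.7% and 99.3% in the strongest.

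Around the marker genes tested below, some regions differed between the libraries as a group. Over 52 regions around stroma and mural cell genes, the median log2 ratio of replicate 2 to replicate 1 was 0.42, outside the middle 95% of random sets matched on signal (−0.21 to 0.20). Around proximal tubule genes it was −0.20 and around endothelial genes −0.23, on the other side of their random ranges. These sets were compared after the data were seen. The random sets drew each region singly from across the genome. Regions of a list cluster around its genes and may vary together, so the random ranges may be too narrow.

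**Figure D2:**
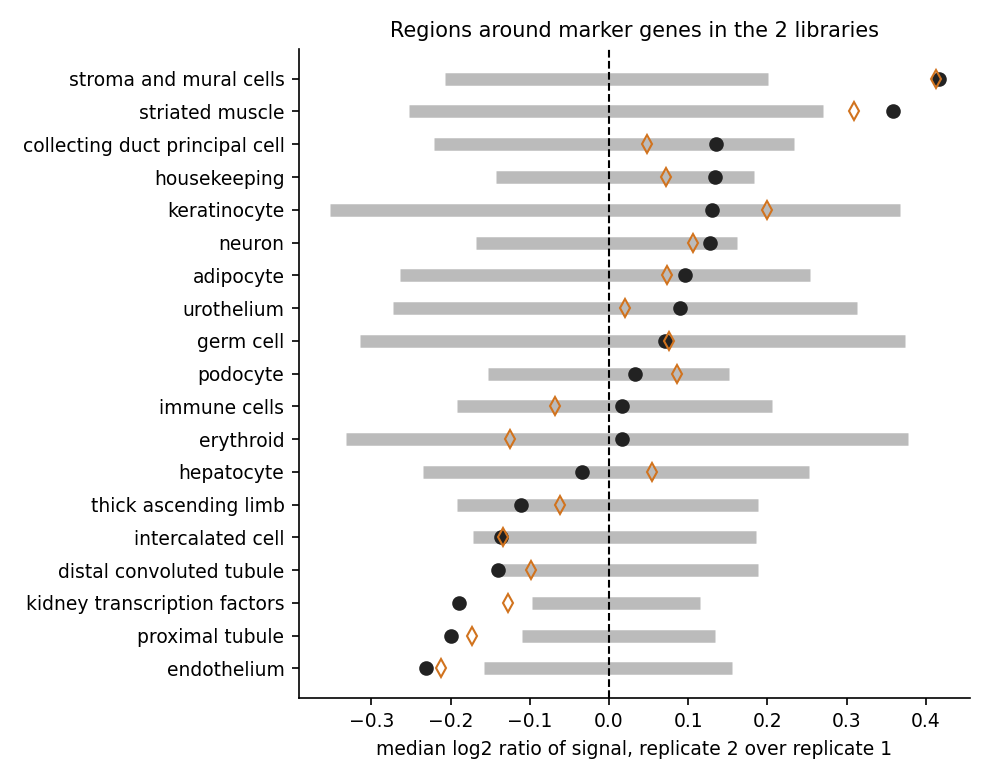
Median log2 ratio of signal, replicate 2 over replicate 1, centred on the median of all shared regions (x axis), for regions around the genes of 19 lists. Filled circles are the medians, open diamonds the medians with the median of each of 20 GC bins taken off, and grey bars the middle 95% of 10000 random sets matched on signal. Stroma and mural cells lie at 0.42 and endothelium at −0.23. The bars may be too narrow, since regions were drawn singly from across the genome.

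Promoters were the most enriched feature. Of the shared regions, 20.01% (95% interval 19.8 to 20.3) overlapped a promoter window, against 1.74% of randomly placed regions. Exons held 10.4%, introns 38.7% and intergenic sequence 30.9%, against 6.92%, 40.5% and 50.8% at random. Promoter regions were also the stronger ones, with a median signal of 2.71 against 0.918 elsewhere. Peaks found in 1 library only lay in promoters less often, at 8.34% (8.06 to 8.62) in replicate 1 and 11.7% (11.3 to 12.1) in replicate 2.

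The next comparison asked which cell types' genes had open promoters in this tissue. Of 21646 protein-coding genes, 13628 (63.0%) had an open promoter. Proximal tubule genes, kidney transcription factors, endothelial genes and housekeeping genes were open more often than other genes. Genes of immune cells, striated muscle, neurons, keratinocytes, urothelium, adrenal cortex, erythroid cells and germ cells were open less often.

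All 18 kidney transcription factor genes had an open promoter (Fisher's exact test, adjusted exact p = 0.00159). Esrra, which encodes a nuclear receptor of energy metabolism, had the strongest, with a signal of 28.6 ± 3.01 (SD, n = 2) at chromosome 19:6921821-6922100. Ppara, the lipid-sensing nuclear receptor, followed with 10.2 ± 0.483 at chromosome 15:85735281-85735720. Tfcp2l1, a transcription factor of the distal nephron and collecting duct, had 6.30 ± 1.39.

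Of the proximal tubule list, 20 of 22 genes were open (adjusted exact p = 0.0119 by Fisher's exact test). Pck1, a key enzyme of gluconeogenesis, led with 7.07 ± 0.780 (SD, n = 2) at chromosome 2:173152541-173153100. Miox, which oxidises myo-inositol, had 5.88 ± 0.563 at chromosome 15:89334261-89334580, and Lrp2, which encodes the endocytic receptor megalin, had 5.39 ± 0.378 at chromosome 2:69585981-69586260. The organic anion transporter gene Slc22a8 and the amino acid transporter gene Slc7a13 had no promoter peak in either library. Within 10 kb of the gene, Slc22a8 had 7 shared regions outside promoters and Slc7a13 had 2. The flank of Slc22a8 takes in part of Slc22a6, another gene of the list, so some of its regions may belong to that gene. With a window of 2000 bases both had a peak, with mean signals of 2.51 and 1.28.

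All 12 endothelial genes were open (adjusted exact p = 0.0106, Fisher's exact test), led by the endocytic gene Ehd3 with 5.15 ± 0.330, the receptor kinase gene Tie1 with 2.56 ± 1.05 and Eng, which encodes endoglin, with 2.36 ± 0.285. All 14 housekeeping genes were open (adjusted exact p = 0.00599), with Rplp0 at 21.03 ± 5.32, Rpl13a at 16.2 ± 1.43 and Actb at 16.2 ± 0.518. In the shorter peak list the proximal tubule call was lost (72.7% open, Fisher's exact test, adjusted exact p = 0.347), as was the endothelial one (83.3%, adjusted exact p = 0.199). The endothelial call was also lost in the stronger 50% of peaks (75%, adjusted exact p = 0.295).

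The lists of the later nephron did not pass the test against all genes, although most of their members were open. In the thick ascending limb 10 of 12 were open (adjusted exact p = 0.272, Fisher's exact test), with Umod, which encodes uromodulin, at 5.35 ± 2.00, Egf at 5.34 ± 0.548 and the potassium channel gene Kcnj1 at 3.67 ± 1.21. The Egf and Kcnj1 peaks lie at an internal TSS, away from the start of the gene. The tight junction gene Cldn19 had no promoter peak. In the distal convoluted tubule 9 of 10 were open (adjusted exact p = 0.137), among them the kinase gene Wnk4 at 5.04 ± 1.45, Emx1 at 4.07 ± 0.0358 and Sgms2 at 2.89 ± 0.476. In the principal cell list, fixed before the data were examined, 11 of 12 were open (adjusted exact p = 0.0613). Scnn1g, a subunit of the epithelial sodium channel, had 5.06 ± 1.22, Tmem213 had 1.62 ± 0.125 and the water channel gene Aqp3 had 1.55 ± 0.209. The Tmem213 region also lies in the promoter window of Atp6v0a4, a proton pump subunit, so its signal may not belong to Tmem213. Whether each listed gene marks principal cells alone was not tested. In intercalated cells 9 of 12 were open (adjusted exact p = 0.615), led by the proton pump gene Atp6v1b1 at 1.47 ± 0.438, Car12 at 1.31 ± 0.0569 and Adgrf5 at 1.07 ± 0.306. The anion exchanger gene Slc4a1 and the water channel gene Aqp6 had no promoter peak. Some of these lists passed under an alternative. In replicate 1 alone all 12 principal cell genes (adjusted exact p = 0.0123, Fisher's exact test) and all 10 distal convoluted tubule genes (adjusted exact p = 0.0274) were open, and with a window of 2000 bases all 12 thick ascending limb genes were (adjusted exact p = 0.0267).

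Podocyte genes were open in 8 of 12 cases (adjusted exact p = 1, Fisher's exact test), with Cdkn1c at 3.33 ± 0.296 and Clic5 at 2.05 ± 0.0231. The slit diaphragm gene Nphs1 had no promoter peak in either library. Stroma and mural cell genes were also open in 8 of 12 cases (adjusted exact p = 1), with Pdgfra at 2.41 ± 1.02, Itga8 at 1.58 ± 1.00 and Myh11 at 1.35 ± 0.337, and with no peak at Acta2 or at Ren1, which encodes renin. A window of 2000 bases reached a peak of Ren1 with a mean signal of 3.62.

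None of the 14 immune genes was open (adjusted exact p = 1.82e-05, Fisher's exact test), including Ptprc, which encodes CD45, and Cd3e of the T cell receptor complex. In striated muscle 1 of 14 was open (adjusted exact p = 0.000226), the calcium release channel gene Ryr2 at 2.22 ± 0.166, while the myosin genes Myh6 and Myh7 had no peak. In neurons 1 of 12 was open (adjusted exact p = 0.000948), Grin1 at 0.474 ± 0.120, with no peak at Snap25 or Syt1. In replicate 2 alone 3 of 14 muscle genes (21.4%) and 2 of 12 neuron genes (16.7%) were open, in replicate 1 alone 3 of 12 neuron genes (25%), and with a window of 2000 bases 3 of 14 muscle genes and 1 of 14 immune genes. These calls held. Neurons had none open in the shorter list and in the stronger 50% of peaks. With a window of 2000 bases the neuron share rose to 75% and the direction turned (adjusted exact p = 0.762). In keratinocytes 1 of 10 was open (adjusted exact p = 0.00349), Krt10 at 6.21 ± 0.404, with no peak at Krt5 or Krt14. The Krt10 peak, at chromosome 11:99385921-99386180, lies at an internal TSS, away from the start of the gene at base 99389364. With 2000 bases 2 of 10 keratinocyte genes were open and the call held.

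Urothelium, adrenal cortex and erythroid lists each had 1 of 8 open (adjusted exact p = 0.0106 each, Fisher's exact test). The open member was Upk3a at 1.10 ± 0.0522 in the urothelium list and Star at 0.975 ± 0.106 in the adrenal list. Upk1a, Upk1b, Cyp11a1, Cyp11b1, Hba-a1 and Hbb-bs had no promoter peak. The urothelium share was 37.5% in replicate 2 alone and with a window of 2000 bases, where the call was lost (adjusted exact p = 0.196 and 0.164). In replicate 1 alone it was 25% and the call held. The adrenal share was 25% in replicate 2 alone and with 2000 bases, and the erythroid share 25% with 2000 bases and 0% with 100 bases, in the shorter list and in the stronger 50%, all with the call kept. In germ cells 2 of 10 were open (adjusted exact p = 0.0120), Dazl at 3.80 ± 0.0480 and Sycp3 at 0.677 ± 0.0371, with no peak at the protamine genes Prm1 and Prm2. Adipocyte genes (3 of 8, adjusted exact p = 0.195) and hepatocyte genes (5 of 14, adjusted exact p = 0.0710) did not pass. Both were called lower in the shorter list (1 of 8, adjusted exact p = 0.0184, and 2 of 14, adjusted exact p = 0.00404) and in the stronger 50% of peaks (1 of 8, adjusted exact p = 0.0384, and 2 of 14, adjusted exact p = 0.00525). Hepatocytes were also called with a window of 100 bases (4 of 14, adjusted exact p = 0.0416) and in replicate 2 alone (5 of 14, adjusted exact p = 0.0439). Germ cells had 1 of 10 open in the stronger 50%. Plin1 had 1.23 ± 0.577, Pparg 0.648 ± 0.192 and Fabp4 0.586 ± 0.0680, with no peak at Adipoq and Cidec. Fga had 1.93 ± 0.340, Apoh 0.964 ± 0.252 and Cyp8b1 0.776 ± 0.189, with no peak at Apoa2 and Fgb. A window of 2000 bases also reached peaks of Apoa2 (1.87), Cldn19 (1.81), Snap25 (1.57), Upk1a (1.43) and Syt1 (0.237), and stronger peaks of Plin1 (7.43), Apoh (4.68), Pparg (2.96), Tmem213 (2.96), Atp6v1b1 (2.46) and Clic5 (2.20).

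**Figure D3:**
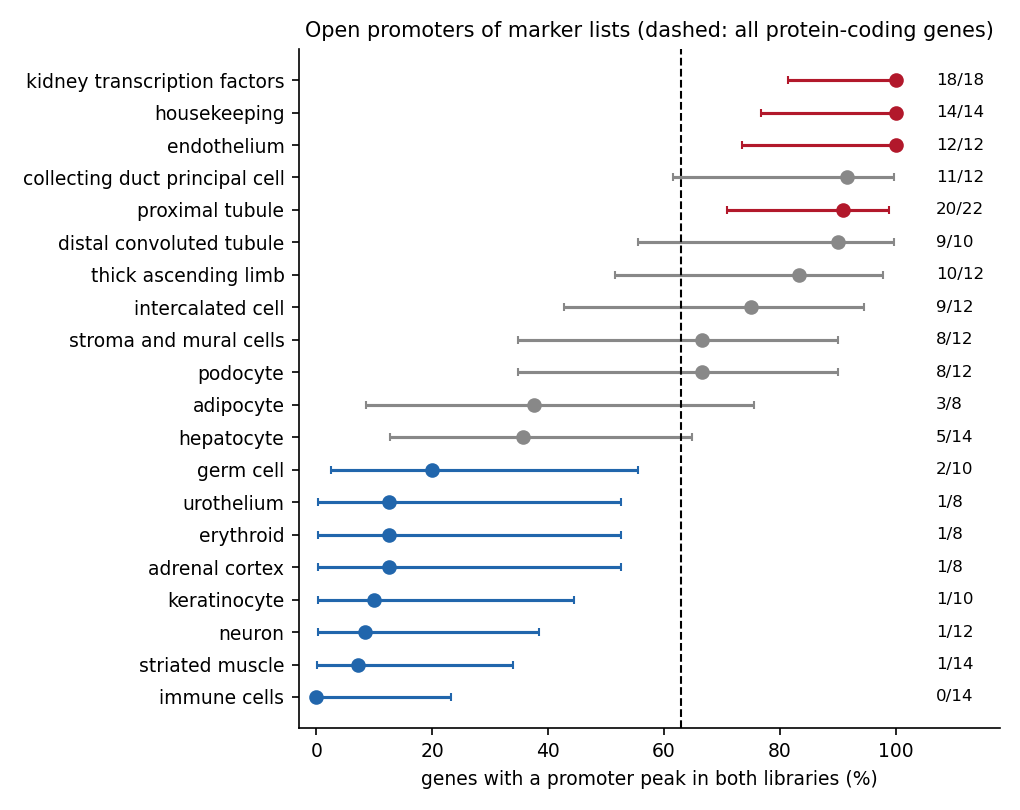
Share of genes with a promoter peak in both libraries (x axis, percent) for each of 20 lists, with exact 95% binomial intervals and the counts at the right. Red lists were open more often and blue lists less often than other genes at an adjusted p under 0.05, grey lists did not pass, and the dashed line is the 63.0% of all protein-coding genes.

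The calls were set against CpG content. Of 10426 genes with CpG-poor promoters 32.03% were open, against 91.7% of the others. Among CpG-poor genes alone, 7 lists were open more often. These were proximal tubule, thick ascending limb (77.8%), distal convoluted tubule (83.3%), principal cells (87.5%), intercalated cells (72.7%), endothelium and kidney transcription factors. Housekeeping genes, of which 3 were CpG-poor, no longer passed (adjusted exact p = 0.0657, Fisher's exact test), with all 3 open. With every member open in both lists and an interval of the odds ratio from 0.877 upwards on 3 genes, a smaller effect is neither shown nor excluded. The lists open less often fell from 8 to 2, immune cells and striated muscle. Of the 6 lower calls that were lost, keratinocytes had 0 of 9 open (odds ratio 0.112, 95% interval 0 to 1.07, against 0.0928 in the whole list), germ cells 0 of 7 (0.141, 0 to 1.47, against 0.173) and neurons 0 of 6 (0.163, 0 to 1.80, against 0.0766). With no CpG-poor member open, these calls ended in shorter lists set against a lower share of other genes, and the values do not show that CpG content caused them. In urothelium and erythroid cells 1 of 8 was open and in adrenal cortex 1 of 7, with odds ratios of 0.424, 0.424 and 0.489 against 0.118 in each whole list. Their intervals are wide (0.00672 to 2.36 in urothelium), so a part played by CpG content stays open. The hepatocyte and adipocyte lists, called lower under some other alternatives, were not lower here. Hepatocytes had 4 of 13 open (odds ratio 1.01, 0.212 to 3.38, against 0.340 in the whole list). Adipocytes had 2 of 7 open (0.965, 0.0808 to 5.19, against 0.374).

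Regions outside promoters were compared around the same lists. A region within 10 kb of several genes, such as the neighbours Slc22a8 and Slc22a6, was counted for each. Proximal tubule genes had a median of 5.5 shared regions in the gene body and 10 kb on each side, against 2 in random lists of like gene length (adjusted p = 0.002 from 10000 random lists, a permutation test, p = 0.0002 before adjustment, the smallest they can give). Kidney transcription factors had a median of 7 against 2.5 (adjusted permutation p = 0.002), with 43 regions around the nuclear receptor gene Esrrg and 13 around Pax8, both chosen after their values were seen. Distal convoluted tubule genes had a median of 8 against 3 (adjusted permutation p = 0.0360). Sgms2 had 12 such regions, Emx1 9 and Wnk4 2. No list had fewer regions than random lists, at an adjusted or an unadjusted p under 0.05. The random range began at 0 for principal cells, urothelium, adrenal cortex, adipocytes, erythroid cells, hepatocytes, striated muscle, germ cells, keratinocytes and housekeeping genes. These lists could not have passed as lower, since no median lies below 0. The erythroid list, at a median of 0, had an unadjusted permutation p of 0.120. The proximal tubule call was lost in the gene body alone (median 1 against 1). The distal convoluted tubule call was lost under all 6 alternatives, among them the gene body alone (4.5 against 2, permutation test, adjusted p = 0.322), a flank of 50 kb (10.5 against 7.5, adjusted p = 0.494) and each library alone (adjusted p = 0.107 without replicate 1 and 0.132 without replicate 2). All 3 calls were lost with the shorter peak list and with the mean in place of the median, where the adjusted permutation p was 0.0600 and 0.0940 for the first 2 lists.

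The genes with the most shared regions had long annotated bodies. Fgfr2, a fibroblast growth factor receptor gene whose annotated body spans chromosome 7:130162451-133123350, had 202 regions, Pde4d 84, Nav2 61, and Camta1, Syn3 and Tns1 59 each. Ank3 and Rora had 58 each. The gene models Gm20388, with 432 regions over chromosome 8:119910841-124345722, and Gm37240, with 61, also ranked here. The promoter regions of Fgfr2, Gm20388 and Gm37240 lie in promoter windows of other genes as well (Ctbp2, Usp10 and Glt28d2). The annotated body of Fgfr2 thus reaches the promoter of Ctbp2. Bodies of such length may take in other genes, so the regions counted may not belong to the named genes.

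The 10 strongest shared regions outside promoters fell into unlike kinds. Regions nearest to Cox14, Tfap4, Nr1d1 and A830005F24Rik had similar signals in both libraries, with ratios of replicate 2 to replicate 1 of 0.731 to 1.15. The region at chromosome 11:98773821-98774220, in an intron 1.11 kb from the TSS of Nr1d1, which encodes the circadian repressor REV-ERB alpha, had 26.1 ± 2.72 (SD, n = 2). The region at chromosome 15:99735641-99736060, 10.0 kb from Cox14 in an annotated exon, had 31.4 ± 3.18. The intergenic region at chromosome 16:4541861-4542080, 10.9 kb from Tfap4, had 30.3 ± 1.31. The other 6 regions were 2.67 to 3.68 times higher in replicate 2. The strongest, in an exon at chromosome 17:39846781-39846920, had 32.2 in replicate 1 and 89.3 in replicate 2, and its nearest protein-coding gene, Esp38, is 104 kb away. The rest were nearest to Gm8797, Igf2bp3, Limd1, Kpna1 and Il31ra. In all 6, most of the 32-base words sampled occur more than once in the genome.

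Footprints were compared next, to ask which transcription factor motifs they hold. The libraries held 316362 and 312966 footprints with a median width of 10 bases, of which 89.3% and 87.0% lay in peaks. Of each library's footprints, 50.9% and 50.8% overlapped one of the other library, against 20.4% and 21.9% for footprints placed at random inside peaks. A control window could be placed for 58732 of 148544 shared footprints (39.5%). Only these were tested, and they may not stand for the rest.

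The motif of CTCF, the insulator protein, had the highest ratio among motifs with control windows. Motifs with no control window have lower bounds only and cannot be ranked against it. CCASYAGRKGGC occurred in 838 footprint windows (1.43%) and in 5 control windows, a ratio of 168 (95% interval 69.6 to 404). The motifs of HNF1 and HNF4, factors of kidney and liver epithelia, were also higher. The HNF4 motif CAAAGTCCA occurred in 256 against 37 windows, a ratio of 6.92 (4.90 to 9.76), and the HNF1 motif in 56 against 0, at least 18.7-fold higher. Other motifs that were higher were NRF1 (75 against 0, at least 25-fold), KLF and SP factors (582 against 33), NFI (45 against 0, at least 15-fold), ETS (ratio 2.68), TFAP2 (2.31) and the estrogen-related receptors (2.03, 1.33 to 3.10). In all, 9 motifs were higher and 3 were lower, FOX (0.289), GATA (0.554) and PU1 (0.658). The AP-1 motif was held by 346 against 336 windows, a ratio of 1.03 (0.887 to 1.20). Footprint windows held 58.3% GC and control windows 53.0%. The test does not correct for this, so the ratios of GC-rich and AT-rich motifs may come partly from base content.

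As a control chosen after the data were seen, each consensus was read backwards. The HNF4 consensus then occurred in 7 against 10 windows and the CTCF consensus in none. The intervals overlapped those of the motif itself for TFAP2 (1.92, 1.67 to 2.21) and the estrogen-related receptors (1.73, 0.918 to 3.27), and for KLF and SP factors (12.4), whose reversed consensus shares most of its bases with the motif. For GATA (0.462) and PU1 (0.255) the reversed consensus was as low or lower. Reversed AP-1 was lower at 0.478 (0.381 to 0.6001) and reversed TEAD at 0.596 (0.432 to 0.822), below the ratios of the motifs themselves (1.03 for AP-1 and 1.14, 0.969 to 1.34, for TEAD), so a ratio near 1 may not mean that a motif is unrelated to footprints. In single libraries, the CTCF ratio was 108 without replicate 1 and 58.7 without replicate 2, the HNF4 ratio 3.71 without replicate 1, the HNF1 ratio 2.75 without replicate 1 (33 against 12 windows) and 9.89 without replicate 2, the KLF and SP ratio 11.4 without replicate 2, and the NRF1 motif occurred in 90 against 1 window without replicate 2. With control windows moved by 50 bases the CTCF ratio was 498, that of KLF and SP factors 41.3, NFI 60 (60 against 1 window) and HNF1 11.2. There 3.46% of 72024 footprint windows held the CTCF motif, so its share depends on which footprints could be given a control window. With no added bases CTCF was at least 264, KLF and SP factors 39.7, HNF4 11.1, FOX 0.0880, GATA 0.288 and PU1 0.283. Outside promoters NRF1 was at least 8-fold higher. PU1 missed the ratio cut in each library alone, at 0.700 without replicate 1 and 0.736 without replicate 2. The estrogen-related receptors, at 1.89 with no added bases, missed the cut on the p-value (Fisher's exact test, adjusted exact p = 0.0651).

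**Figure D4:**
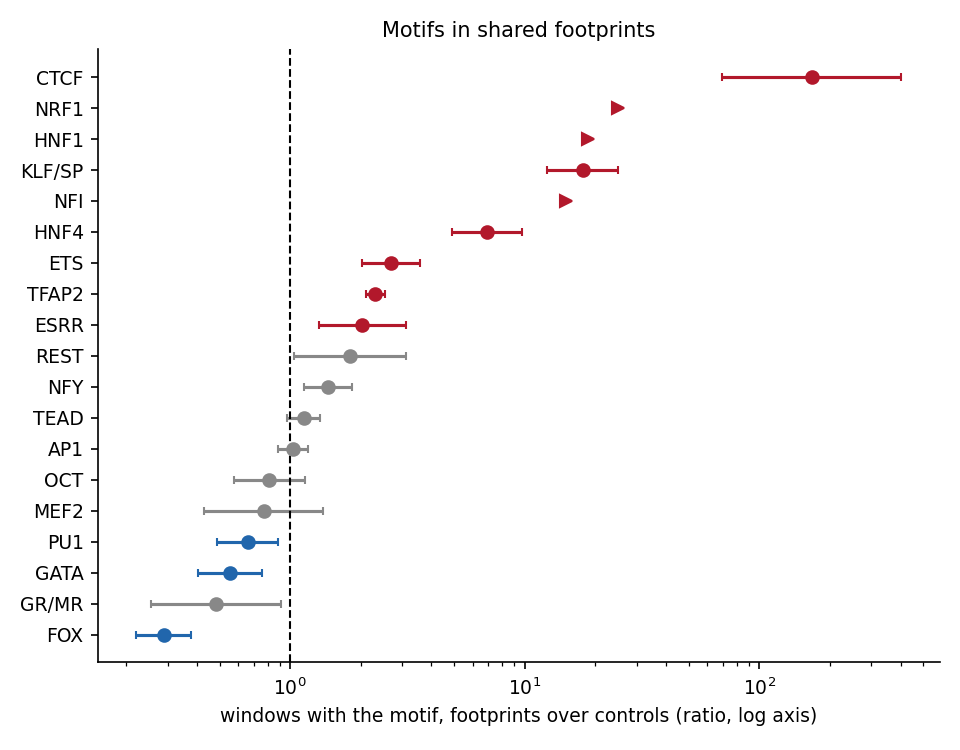
Ratio of windows holding each motif in shared footprints over control windows (x axis, log scale) with 95% intervals, for motifs seen in at least 40 windows. Red motifs were called higher, blue lower and grey neither, and arrowheads mark lower bounds for motifs with no control window. CTCF lies at 168 and FOX at 0.289.

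The last comparison was between chromosomes. Xist, the RNA gene that silences an X chromosome in females, had an open region at X:103483141-103483360 with a signal of 1.54 in replicate 1 and 2.01 in replicate 2. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had no promoter peak in either library. The X chromosome held 13.6 shared regions per Mb (95% interval 13.1 to 14.2), against 39.4 (39.2 to 39.7) on the autosomes, a ratio of 0.345. Per protein-coding gene it held 2.35 against 4.57, a ratio of 0.515. On the X, 44.8% of genes had an open promoter.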

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

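In this part, the tests on strong peaks found in 1 library only were chosen after the result was seen. Apart from a region closed in the other library, no biological explanation was tested for any pattern, since the design has 1 group.

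Both libraries are from females, yet 11 shared regions lay on chromosome Y. The number exceeds the limit of 3 set for a count of 0, which covers counting error only and is no test of misplaced reads. The gene list tests and the X to autosome ratios do not use these regions, although they are counted among the shared regions. The strongest, at Y:90744541-90744780, had a signal of 5.39 in replicate 1 and 2.08 in replicate 2. In all 11 regions, most of the 32-base words sampled occur more than once in the genome.

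A further signal came from the FDR files, which the main peak comparisons do not use. Of the peaks missing from the other library's list, 6756 of 37877 in replicate 1 (17.8%) and 4245 of 26041 in replicate 2 (16.3%) held bases with an FDR under 0.05 in the other library, and the rest, most of them with a signal under 0.5, held none. The pattern is sharpest among strong peaks. Of 507 unshared peaks with a signal of 2 or more, 88.0% held such bases in the other library and 12.03% held none. For most of these peaks, this argues against a stretch wholly closed in the other library. It cannot exclude a closed site within the peak, since 1 such base was enough and may belong to a neighbouring peak. Peak boundaries placed differently remain a candidate explanation, and 80.3% had a peak of the other library within 200 bases. For the 61 peaks without such bases a real difference between the samples stays open too.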

How the results depend on the processing

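The alternative that also counts an FDR under 0.05 in the other library, and the motifs read backwards, were chosen after the data were seen. No paired analysis was possible because there is 1 group. The better 50% of footprints by the authors' value could not be taken, since that value is constant, and a share of shared peaks or footprints has no value in a single library. The cause of the changes below was not tested unless the setting itself gives it. The mean number of peaks per library, 131042, fell to 86585 in the shorter list and 65521 in the stronger 50% by construction. The mean share of shared peaks, 75.8%, was 63.2% with 50% reciprocal overlap and 81.6% in the stronger 50%, and 76.9% to 79.9% with the shorter list, equal numbers of peaks or the FDR counted. The Pearson r of log2 signal was 0.896. The promoter share was 14.9% with a window of 100 bases, 28.2% with 2000 bases, 25.1% in the shorter list, 29.7% in the stronger 50% and 16.7% to 18.2% in single libraries. The number of lists with more open promoters, 4, became 2 in the shorter list and 7 among CpG-poor promoters, and that with fewer, 8, became 2 among CpG-poor promoters. The number of lists with more regions outside promoters, 3, became 1 in the gene body alone and 0 with the shorter list or the mean. The mean share of shared footprints, 50.8%, was 36.8% with 50% reciprocal overlap. The X to autosome ratio was 0.320 outside promoters and 0.379 to 0.386 in single libraries. The counts of motifs called stayed within 1.5 times, at 8 to 13 higher and 2 to 4 lower.

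Directions turned for lists and motifs that had not passed the test, and for neurons, which had (75% open with 2000 bases). In the shorter list, thick ascending limb (58.3%), intercalated cells (41.7%), podocytes (50%) and stroma (33.3%) fell below other genes, as did principal cells (41.7%), intercalated cells (25%) and stroma (25%) in the stronger 50%. Region counts turned for intercalated cells in the gene body (0.5) and, with the mean, for stroma (3.08), striated muscle (1.86) and germ cells (1.10). Motif ratios turned for GRHL (1.29 with controls moved by 50 bases, 0.870 to 1.93 in single libraries), MEF2 (1.17 with controls moved by 50 bases), TEAD (0.819 with no added bases) and OCT (1.02 outside promoters, 0.888 to 1.03 in single libraries). Apart from those that turned, of 140 results for single lists at promoters, 12 lost and 13 gained a call. Of 120 around genes, 11 lost one. Of 125 for single motifs, 3 lost and 11 gained one. Of 438 promoter signals of named genes, 32 moved by more than the spread between libraries. Of the 44 named list genes with an open promoter, 38 kept it in the shorter list. Precision is limited by the 2 libraries and by lists of 8 to 22 genes, where 1 gene moves a share by as much as 12.5 percentage points.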

Other observations

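The gene families here and their test, and the test on the share of tubule cells, were chosen after the result was seen. Apart from that share, no biological explanation was tested, since the design has 1 group.

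Gene families were taken by the start of the gene symbol, and some of their members are also in the fixed lists. They differed too in how often their promoters were open (Fisher's exact test, adjusted over 13 families). Solute carriers, the membrane transporters that include most nephron transporters, were open in 282 of 371 cases (76.0% against 62.7% of other genes, adjusted exact p = 1.27e-07). Among CpG-poor genes the shares were 60.6% against 31.5% (adjusted exact p = 3.41e-14). Subunits of the proton pump V-ATPase were open in 22 of 23 cases (adjusted exact p = 0.00102) and in 7 of 8 CpG-poor cases (adjusted exact p = 0.00429). The symbol prefixes of NADH dehydrogenase subunits and of cytosolic ribosomal proteins also match other genes. Among these are assembly factors of the dehydrogenase and kinases named after a ribosomal protein. Genes with the first prefix were open in 45 of 46 cases and those with the second in 89 of 98 (Fisher's exact test, adjusted exact p = 6.32e-08 and 1.54e-09). Neither group passed among CpG-poor genes (adjusted exact p = 0.0726 and 0.616). There, genes with the NADH dehydrogenase prefix were open in 4 of 5 cases, against 32.003% of other genes. The odds ratio was 6.37 (95% interval 0.840 to 419) after 17.9 among all genes, too few genes to tell. Genes with the ribosomal protein prefix fell to 5 of 13 (38.5%), with an odds ratio of 1.37 after 5.57.

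Olfactory receptor genes were open in 9 of 1133 cases and vomeronasal receptor genes in 2 of 330. Keratins (7 of 53) and defensins (5 of 64) were also open less often, and all 4 of these families stayed lower among CpG-poor genes. Claudins (13 of 33), cytochrome P450 genes (44 of 100) and potassium channel genes (45 of 94) were lower against all genes (adjusted exact p = 0.00763, 0.000253 and 0.00469) and did not pass among CpG-poor genes (0.677, 0.371 and 0.616), where their odds ratios were 0.816, 1.30 and 1.23 after 0.387, 0.462 and 0.539. Hox genes were open in 23 of 39 cases (adjusted exact p = 0.621), with 8 of 11 in the Hoxa cluster, 6 of 10 in Hoxb, 3 of 9 in Hoxc and 6 of 9 in Hoxd.

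The libraries differed around marker genes of certain cell types. Around stroma and mural cell genes, the median log2 ratio of replicate 2 to replicate 1 over 52 shared regions was 0.42. This lay above the middle 95% of 10000 random sets of regions matched on signal (−0.21 to 0.20). All 8 open stroma promoters, which are among these regions, had the higher signal in replicate 2. The rise was largest at Itga8 (2.28 against 0.868) and Pdgfra (3.13 against 1.69) and smallest at Pdgfrb (0.725 against 0.653). Of the housekeeping promoters, 10 of 14 were higher too, and these promoter counts were not adjusted for GC content. Around proximal tubule genes the median log2 ratio was −0.20 over 152 regions, below the middle 95% (−0.11 to 0.13). Around endothelial genes it was −0.23 over 98 regions, also below (−0.16 to 0.16). Of the 19 lists with at least 10 regions, striated muscle (0.36) also lay above and kidney transcription factors (−0.19) below. The random sets ignore that regions of a list cluster around its genes and may vary together. Their ranges may therefore be too narrow.

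GC content is argued against as the whole cause of these medians. With the median of each of 20 GC bins taken off, the stroma median was 0.41 and the proximal tubule median −0.17. Both were little changed and still outside the random range. A single gene is argued against too, since the lowest stroma median with any of the 12 genes left out was 0.32. A lower share of tubule cells in replicate 2, with all other cell types kept in proportion, would raise endothelial regions too. The endothelial median of −0.23 argues against that form only. It cannot decide on a lower tubule share that came with changes among the other cell types. A larger share of stroma in the tissue piece of replicate 2, or a difference between the samples within stroma, may remain, and neither was tested.

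The 6 strongest regions outside promoters that were over 2-fold higher in replicate 2 were all made mostly of repeated words, and the 4 others were not. Reads from repeated sequence are a candidate explanation that the wider set leaves open. Among regions ranked 11 to 500, the 11 mostly repeated ones had a median ratio of 1.29, against 0.952 for the 479 others, which is below the 2-fold the explanation needs and above 1. Of the 9 regions there with a ratio over 2, 2 (22.2%, exact 95% interval 2.81 to 60.01) were mostly repeated. The repeated regions are too few to decide, and why replicate 2 would hold more such reads was not tested.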
